A study of Mus musculus with 4 samples.

How the data were processed

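RNA from pooled superior cervical and stellate ganglia of adult mice was sequenced in 4 samples, per the labels: a control and a mutant of the Hand2 line and a control and a mutant of the Gata3 line, 1 pool each. The controls of both lines carried a floxed and a wild-type allele, the Hand2 mutant a floxed and a deleted allele and the Gata3 mutant only floxed alleles, per the labels. The submitters' processing notes list TopHat2 2.0.8, SAMtools 0.1.19, HTSeq 0.5.4p1 and DESeq without a version, and the mouse build mm9, with no role or settings. The annotation, the strand setting and the treatment of reads with several positions are not given in the sources used here. Antisense and overlapping genes and near-identical copies, such as ribosomal protein pseudogenes, amylase genes and serpin clusters, are therefore uncertain.

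The single table used here lists 21937 genes by symbol. Per the file headers it holds the columns of a DESeq comparison, namely a value headed mutant expression, a value headed control expression, a second group mean, a fold change, its log2, a p-value and an adjusted p-value. Per the file headers, by DESeq's naming, the deposited control column and the second group mean are means of reads divided by size factors, and they were treated as a normalised score with no stated unit. In all 21937 genes the column headed mutant expression equals the mean of those columns, so the authors' heading does not match its content and that column was not used as a mutant value. The fold change in the authors' table equals the second group mean divided by the control value in all 16990 genes that have a fold, to a relative tolerance of 1e-09. The authors' p-value and adjusted p-value columns were copied and not recomputed. The deposited log2 column was not used, because part of its cells hold spreadsheet errors.

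The deposited values are whole numbers, and were at first taken for read counts. The treatment as normalised values replaced this after the results had been seen, on a second look prompted by a check of the files, which does not take count columns that are assigned to no sample. The median ratio of the columns over the 15859 genes above 0 in both was exactly 1, and 600 genes had equal values above 0. Each whole number from 1 to 100 was held by at least 10 genes in each column, so there was no trace of a single unequal scaling. A single library scaled up and then rounded would leave gaps, unless its factor was very near 1. Scaling down, or averaging rescaled libraries before rounding, would leave none. How many libraries entered each column is not given in the sources used here. Neither reading is excluded, and the values were not used as counts. Counting intervals and floors, computed under the first reading, were left out, and whether the column sums are read totals is not known. The control column (side A) summed to 19343986 and the second group mean (side B) to 19135221. The 10 highest genes took 4.25% and 3.99% of these sums, and 4947 genes were listed at 0 in both.

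No column could be matched to a sample, because the table names neither the line nor whether the lines were combined. The plan made before the data were examined had separate Hand2 and Gata3 comparisons, a comparison of the controls, genes shared by both lines and a fit across both lines. None of these could be run on a single comparison of 2 columns, and the planned measures of size were applied to side B against side A. Genotypes were not inferred from the values of Hand2 or Gata3.

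For each gene the log2 ratio of B to A was computed with a pseudocount of 1, which understates the ratios of low genes. Genes with a mean value of at least 50 and a ratio of at least 2-fold on this scale were counted as higher or lower. Folds of single genes are plain ratios of the deposited values, and none is given against a value listed at 0. With 1 column per side no p-value was computed. Each gene's log2 ratio was also placed among those of the 500 genes nearest to it in rank of mean value, as a description and not a replicate error. This ranking was not planned, and it replaced counting intervals after the results had been seen.

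The 29 gene lists fixed before the data were examined covered neuronal functions, other cell types and cell states. A member was detected at a mean value of at least 20. For lists with at least 5 detected members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched in 10 bins of mean value, as a description. Of 647 list entries 642 matched a symbol of the table, directly or through a synonym. The 6 further lists, namely X escape genes, other skeletal muscle genes, other sensory neuron genes, other nuclear-retained transcripts, nuclear and splicing-related transcripts seen lower and MHC class II genes, were drawn up after the table had been seen.

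Genes were named by a rule fixed beforehand. It took Hand2, Gata3, Th and Dbh, and in each list up to 4 detected members with the largest absolute log2 ratio. It also took the 12 genes with the largest and the 12 with the smallest ratio at a mean value of at least 50. In use, these largest and smallest were limited to genes past the 2-fold rule, a limit that was not in the plan. Predicted genes, small RNAs, haemoglobins and immune receptor segments were left out of the largest and smallest. Only 4 genes were 2-fold higher, and 1 of them is not described here. The parts of the rule for genes shared by both lines could not be used. Genes named outside the rule are said to have been chosen after their values were seen.

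Transcript length and GC content came from the GENCODE vM21 transcripts of GRCm38, matched by symbol, taking the longest transcript of each gene. Of the 21937 symbols, 19390 (88.4%) matched this annotation. No coordinates are given, because this build differs from mm9. The correction subtracted the median log2 ratio of genes in the same of 20 bins of length or GC content.

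The alternatives were scaling by column totals, ratios centred on their median, a pseudocount of 5, minimum means of 20, 200 and none, ratios of 1.5 and 3, and for lists a detection minimum of 100 and random lists not matched on expression. Planned scalings that model read counts were run while the values were taken as counts and were then left out. The numbers of genes without members of the sex-linked, muscle, sensory and nuclear-retained lists were added after seeing the data. A gene's value was taken as moved by a setting when it shifted by more than the SD of its like genes, a limit chosen after the results had been seen. The size rule was tested on simulated data made from the means of side B and side A with 200 genes changed, drawn as if the means were counts with a small assumed spread between libraries. It recovered 96.0% of genes changed 3-fold and 4.50% of those changed 1.5-fold, which lie under the 2-fold rule, and called 4 unchanged genes in either run. Of 200 simulated unchanged lists, 10 (5.00%) lay outside the central 95%. Their members were drawn at random from genes simulated independently, so a share near this was fixed by construction. It does not cover lists of related genes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.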

Results

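Gene expression was measured by RNA sequencing in superior cervical and stellate ganglia, the paired sympathetic ganglia of the neck and upper thorax, of adult mice at postnatal day 60. The series asked what the transcription factors Hand2 and Gata3 do in mature noradrenergic neurons. Each gene was targeted in a line of its own by a tamoxifen-dependent Cre recombinase driven by the promoter of dopamine beta-hydroxylase (Dbh). Tamoxifen was injected for 10 days. Per the labels, the Hand2 mutant carried a floxed and a deleted allele, and the Gata3 mutant only floxed alleles. The controls of both lines carried a floxed and a wild-type allele. The series has 4 samples, each the only pool of its genotype. The Hand2 control, the Hand2 mutant and the Gata3 control each pooled 16 ganglia from 4 mice. The Gata3 mutant, in which the series' design text describes ganglion rudiments, pooled 32 ganglia from 8 mice.

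The deposited table holds a single comparison of 2 columns of expression values, treated here as normalised, and does not name the line, nor whether the lines were combined. The column headed control is called side A here, and the column set against it is called side B. The sheet sets a mutant against a control, so side B is read as the mutant side, but the mutant heading itself stands over the mean of both columns. No genotype was assigned to side B from its values. The values of side A summed to 19343986 over 16501 genes and those of side B to 19135221 over 16348 genes. Whether these sums are read totals is not known, since the values are not known to be read counts, and no counting error is given. With 1 column on each side no difference has a replicate check, and "higher" and "lower" describe these columns. Each gene's ratio was ranked among the 500 genes closest to it in mean value, called like genes, a yardstick chosen after the results had been seen.

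Hand2, a basic helix-loop-helix factor of the noradrenergic lineage, had a value of 4749 on side A and 2001 on side B, 2.37-fold lower (log2 ratio -1.25), at percentile 0.20 of its like genes. The authors' deposited table gives Hand2 an adjusted p of 1.53e-15. Gata3, a zinc finger factor of the same lineage, had values of 1105 and 1050, a ratio of B to A of 0.950, at percentile 27.0 of its like genes. A total per gene does not separate the exons that Cre removes from those it leaves. The series' design text states that Gata3 was not lower in the rudiments of the Gata3 mutant, and no line was assigned to the table from either value.

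Few other genes differed by much between the sides. Of 12043 genes with a mean value of at least 50, 11784 (97.8%) lay within 1.5-fold, and the log2 ratio of B to A had a median of 0.0026 and an SD across genes of 0.31. At a ratio of at least 2-fold, 4 genes were higher on side B and 54 were lower. Among the higher genes were Xist, Ly86 and Oprk1. Oprk1, the kappa opioid receptor gene, had values of 43 and 90. The authors' deposited table gives Ly86 and Oprk1 an adjusted p of 1.0. In simulated data the same rule called 4 unchanged genes, counting both directions. That simulation assumed a small spread between libraries, so it does not estimate how many of the genes called here are false. The 12 lower genes with the smallest ratios held 4 Y-linked genes, 7 genes of skeletal muscle fibres and the vesicular glutamate transporter gene Slc17a6. Without the members of the sex-linked, skeletal muscle, sensory neuron and nuclear-retained lists, a selection made after their values were seen, 3 higher and 25 lower genes were left. Genes of these classes outside the lists remained among the 25, such as the muscle genes Des, Tpm2, Ankrd23 and Asb2 and the noncoding Ipw, named after their values were seen. A minimum mean value of 20 in place of 50 gave 22 higher and 110 lower genes.

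**Figure D1:**
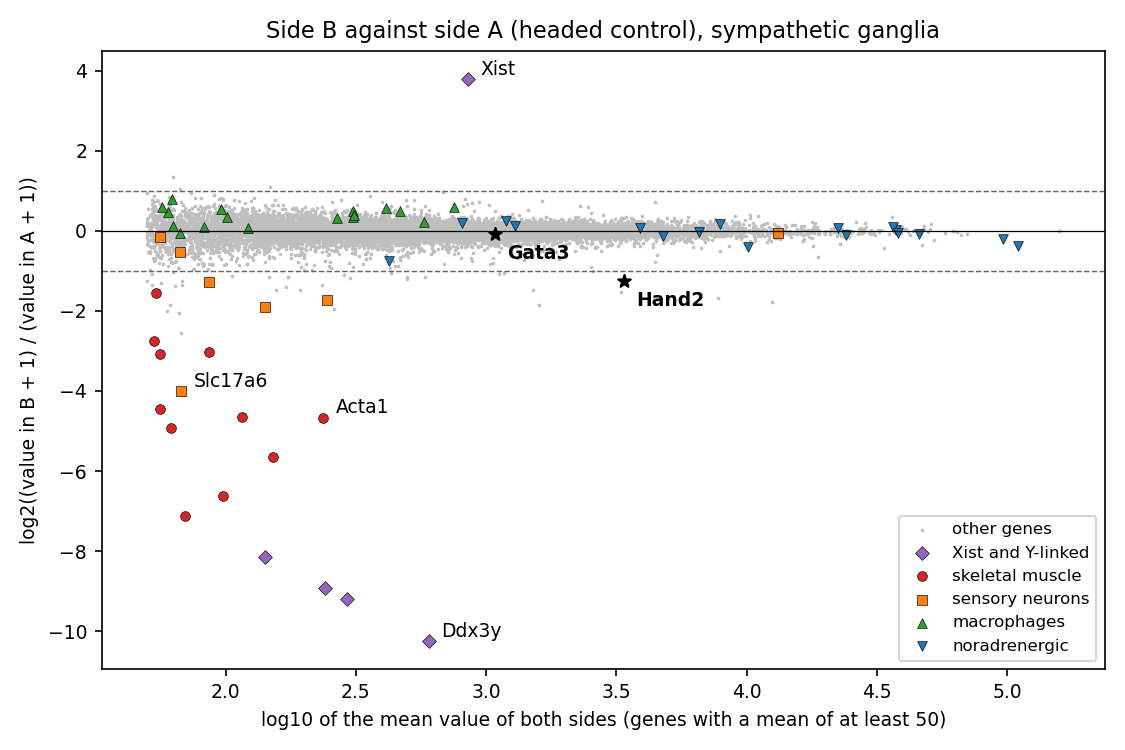
Each point is a gene with a mean value of at least 50; the horizontal axis is the log10 of its mean value over both sides and the vertical axis is its log2 ratio of side B to side A with a pseudocount of 1, with dashed lines at 2-fold. Hand2 lies at -1.25 and Gata3 at -0.07, while Y-linked and skeletal muscle genes reach the lowest ratios and Xist the highest.

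The sides differed in sex-linked transcripts. Xist, the noncoding RNA that coats the inactive X chromosome, had a value of 114 on side A and 1595 on side B, 14.0-fold higher, and the authors' deposited table gives it an adjusted p of 5.55e-58. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had values of 1206, 587, 483 and 282 on side A and were listed at 0 on side B. No fold is given against a listed 0. These were the 5 detected members of the sex-linked list.

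Transcripts of skeletal muscle were lower on side B. All 14 detected members of the muscle list lay under the central 95% of their like genes, 11 of them met the 2-fold rule, and their values summed to 2152 on side A and 131 on side B. Acta1, the skeletal alpha-actin gene, had values of 456 and 17, 26.8-fold lower. Atp2a1, the calcium pump of fast fibres, had 300 and 5, and the myosin heavy chain gene Myh1 had 195 and 1. Mb, which encodes myoglobin, had 139 on side A and was listed at 0 on side B. Tnnc2, Tnnt3 and Tnni2, which encode subunits of the fast-fibre troponin complex, had 120, 223 and 108 on side A and 3, 8 and 4 on side B. The list's median log2 ratio was -4.22, at the 0th percentile of 10000 random lists matched on size and expression.

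Transcripts typical of sensory neurons were also lower on side B. Slc17a6 had a value of 128 on side A and 7 on side B, 18.3-fold lower. Scn10a, a sodium channel of nociceptors, had 224 and 59, and the irritant receptor genes Trpv1 and Trpa1 had 74 and 18 and 51 and 5. Trpv1 and Trpa1 lay under the minimum mean value of the 2-fold rule, and the authors' deposited table gives them adjusted p of 0.702 and 0.262. All 9 detected members were lower, 6 lay under the central 95% of their like genes and 4 met the 2-fold rule, and the median log2 ratio was -1.73, at the 0th percentile. Scn10a, Scn11a and P2rx3 are shared with the lists of channels and receptors, and Avil, named after its values were seen, was abundant on both sides at 13534 and 12975. The differences in sex-linked, muscle and sensory transcripts lay between the same sides as every other group compared.

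The noradrenergic list did not stand apart from random lists in its median. Its 17 detected members, 8 higher and 9 lower, had a median log2 ratio of -0.02, at the 36.5th percentile, and none differed by 2-fold. Under the central 95% of their like genes lay 3 members, Slc6a2, Chgb and Slc18a1, at percentiles 1.6, 1.2 and 1.0, and none lay above. Th, the rate-limiting enzyme of catecholamine synthesis, had a value of 47123 on side A and 44280 on side B, a ratio of 0.940, at percentile 21.2 of its like genes. Dbh, which converts dopamine to noradrenaline, had 102922 and 89194, a ratio of 0.867, at percentile 4.80. Slc6a2, the noradrenaline transporter gene, had 125271 and 95865, a log2 ratio of -0.39, with an adjusted p of 0.175 in the authors' deposited table. Slc18a1, a vesicular monoamine transporter gene listed beside Slc18a2, had 533 and 314, a log2 ratio of -0.76. The granin gene Chgb had 11500 and 8698, a log2 ratio of -0.40. In the authors' deposited table the adjusted p of Slc18a1 and Chgb were 0.368 and 0.211.

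Genes of cholinergic transmission had members in either direction. Vip, a neuropeptide made by cholinergic sympathetic neurons, had a value of 1216 on side A and 2049 on side B, 1.69-fold higher, with an adjusted p of 0.00154 in the authors' deposited table. Ret, the receptor tyrosine kinase for ligands of the GDNF family, had 22966 and 14655, a log2 ratio of -0.65, with an adjusted p of 4.21e-05 in the authors' deposited table. Chat, the acetylcholine synthesis gene, had only 28 and 34. The list's 12 detected members, 4 higher and 8 lower, had a median of -0.03, at the 24.5th percentile.

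Autonomic transcription factors other than Hand2 differed little. The 16 detected members, 5 higher and 11 lower, had a median log2 ratio of -0.08, at the 2.48th percentile, and without Hand2 the median of the other 15 was -0.07, at the 4.90th percentile. Ebf1 had values of 506 and 396 (log2 ratio -0.35), Sox4 had 775 and 659 (-0.23) and Hmx1 had 581 and 655 (0.17). The list's place below the central 95% of random lists was lost without matching on expression, at the 3.71st percentile.

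Structural and synaptic neuronal genes were slightly lower on side B. The pan-neuronal list of 18 genes had a median log2 ratio of -0.09, at the 0.33rd percentile, with 14 members lower and 4 higher. Its lowest ratios belonged to the neurofilament genes, with Nefm at 9237 and 6554, Nefl at 10990 and 8736 and Nefh at 5708 and 4583. The synaptic vesicle list of 24 genes had a median of -0.07, at the 0.95th percentile, with 17 members lower and 7 higher. Sv2c, a synaptic vesicle glycoprotein gene, had a log2 ratio of -0.43 and the complexin gene Cplx2 had -0.42.

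Ion channels were lower more often than higher. Of 90 detected genes of the sodium, potassium, calcium and hyperpolarization-activated channel families, 63 were lower and 26 higher, and the median log2 ratio was -0.12, at the 0th percentile. The family list also takes in potassium channels not gated by voltage and the noncoding transcript Kcnq1ot1. Without Kcnq1ot1, Scn10a and Scn11a, left out after their values were seen, the other 87 had the same median of -0.12. Kcnab1, an auxiliary subunit of potassium channels, had 1527 and 720, a log2 ratio of -1.08, with an adjusted p of 1.37e-06 in the authors' deposited table. Among 19 detected ligand-gated receptors the median was -0.07, at the 2.94th percentile, and the lowest ratios included P2rx3, a purinergic channel of sensory neurons, at 377 and 113. Htr3b, a serotonin receptor channel subunit, had 5460 and 3610, with an adjusted p of 0.00337 in the authors' deposited table.

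The neuropeptide and granin list had a higher median on side B, a log2 ratio of 0.15 over 12 detected members, at the 99.5th percentile. The granin genes Chga and Chgb were counted in the noradrenergic list instead, where Chgb was lower. There were 9 higher and 3 lower members, and 4 of the higher, among them Vip and Cartpt (101 and 151), lay above the central 95% of their like genes. Vgf, a secreted granin-like precursor, had 2267 and 1634. Neurotrophic factor receptors had a median of -0.03 over 16 genes, at the 28.7th percentile, and Ngfr, the p75 neurotrophin receptor gene, had 52763 and 41600 (log2 ratio -0.34). The axon injury list had a median of 0.08 over 17 genes, at the 97.0th percentile. Its members Npy (9658 and 12494) and the syndecan gene Sdc1 (119 and 186) had higher values on side B, and Atf3 had 57 and 44.

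Among other cell types of the ganglion, macrophage genes were higher on side B. Of 18 detected members 17 were higher, and the median log2 ratio was 0.44, at the 100th percentile. None of these 18 had an adjusted p under 0.05 in the authors' deposited table. The lysozyme gene Lyz2 had values of 599 and 901, the complement gene C1qb had 333 and 494, the Fc receptor gene Fcgr1 had 45 and 79 and Cd14 had 45 and 69. Ly86, which encodes a secreted partner of the Toll-like protein CD180, had 35 and 90, 2.57-fold higher, with an adjusted p of 1.0 in the authors' deposited table. Satellite glia and Schwann cell genes had a median of 0.03 over 25 genes, at the 83.7th percentile, with Fabp7, a fatty acid binding protein of satellite glia, at 7833 and 10171. Endothelial genes had a median of 0.04 over 17 genes, at the 69.4th percentile. No T or B lymphocyte gene reached a mean value of 20.

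Connective tissue and fat genes were lower on side B. The fibroblast list had a median log2 ratio of -0.13 over 18 genes, at the 0.28th percentile, with the matrix genes Postn at values of 2784 and 2057 and Col1a1 at 2643 and 1988. The adipocyte list had a median of -0.24 over 13 genes, at the 0.07th percentile, with the lipase gene Lpl at 844 and 582. Cfd, which encodes adipsin, went the other way with 457 and 903, and the authors' deposited table gives it an adjusted p of 0.00154. Smooth muscle and pericyte genes had a median of -0.06 over 12 genes, at the 19th percentile, and Des, which skeletal muscle also expresses, had 96 and 26. Carotid body genes had a median of -0.15 over 5 genes, at the 4.19th percentile. The salivary list had 2 detected members, Cdh1 (253 and 461) and Amy1 (336 and 131), and the red blood cell list had 2, Alas2 (109 and 144) and Bpgm (573 and 678).

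Interferon response genes were lower on side B as a group. Of 19 detected members 18 were lower and 12 lay under the central 95% of their like genes, and the median log2 ratio was -0.45, at the 0th percentile, though no member differed by 2-fold. The antiviral genes Rsad2, Usp18 and Mx1 had values of 593 and 324, 431 and 243, and 154 and 87, and the interferon regulatory factor gene Irf7 had 553 and 325. No member of the interferon list had an adjusted p under 0.05 in the authors' deposited table. Ribosomal protein genes were higher, with a median of 0.20 over 70 genes, at the 100th percentile, and 66 members higher and 3 lower. Their transcripts are short, and after correction for transcript length the median over the 68 with a length was 0.09. Near-identical pseudogenes make the values of single ribosomal protein genes uncertain.

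Immediate early genes had a median of -0.05 over 16 genes, at the 23.7th percentile, with 6 members higher and 9 lower. Egr1 had a value of 392 on side A and 115 on side B, Fos had 230 and 82, Fosb had 54 and 11, and Klf4 had 66 and 99. The authors' deposited table gives Egr1 an adjusted p of 2.52e-05, Fos 0.0468, and Fosb and Klf4 1.0, and Fosb lay under the minimum mean value of the 2-fold rule. Cell division genes had a median of 0.06 over 11 genes, at the 70.2nd percentile, and apoptosis genes had -0.06 over 16 genes, at the 14.0th percentile. No symbol matched the mitochondrially encoded list.

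**Figure D2:**
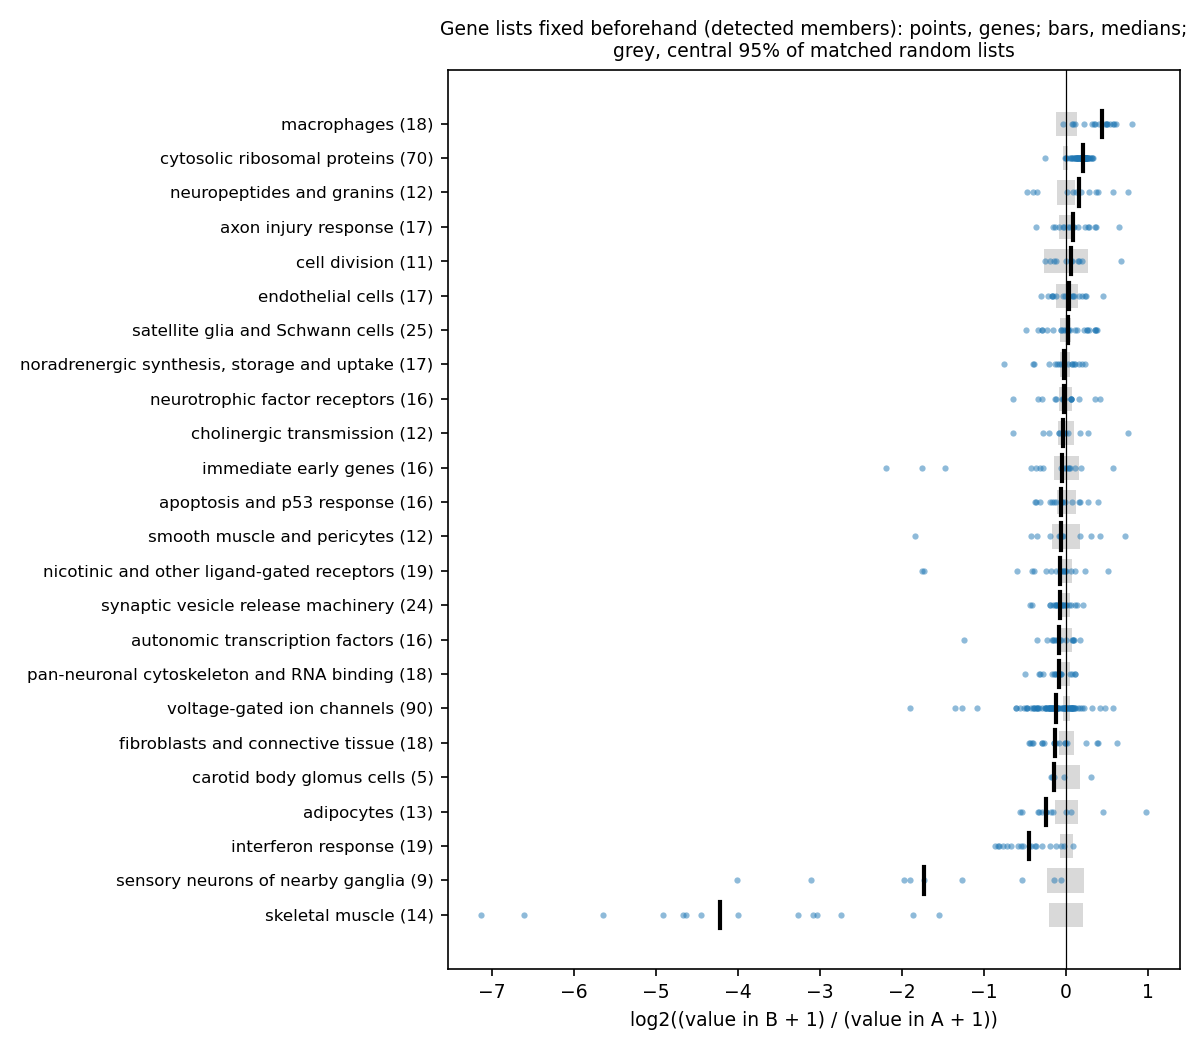
Log2 ratio of side B to side A for the detected members of 24 gene lists, the sex-linked list left out; points are genes, black bars are medians and grey boxes span the central 95% of 10000 random lists of the same size and expression. Skeletal muscle (-4.22) and sensory neuron genes (-1.73) have the lowest medians and macrophage genes (0.44) the highest.

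In all, 25 lists had at least 5 detected members and 13 of them lay outside the central 95% of their random lists, 10 below and 3 above, where 1.25 would lie outside if members were unrelated. Genes of a list share cells and regulation, so these percentiles describe these columns and are not tests of genotype.

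The authors' deposited table gives 62 genes an adjusted p under 0.05, 8 of them higher on side B and 54 lower. Of the 62, 37 also met the 2-fold rule, 1 higher and 36 lower. Counted by list members, with Eif2s3x added to the sex-linked genes, the 62 included 11 skeletal muscle genes, 6 sex-linked genes, 3 sensory neuron genes and 17 nuclear-retained or splicing-related transcripts, the last a group drawn up after its values were seen. The muscle genes Tcap and Mybpc1, in none of the lists and named after their values were seen, were also among the 62. At an unadjusted p under 0.05 the authors' deposited table lists 348 genes, 80 higher and 268 lower. The number of libraries behind each column is not given, so whether these p-values rest on more than 1 pool per side is not known. The series holds no replicate pool of any genotype.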

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

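The numbers of genes without members of the sex-linked, muscle, sensory and nuclear-retained lists and the limit for single genes, the SD of like genes, were chosen after seeing the data, and the other alternatives before. Scaling by column totals, centring and a pseudocount of 5 gave 3 or 4 higher and 53 or 54 lower genes, all among the 4 and 54 reported. A minimum mean value of 20 gave 22 higher and 110 lower genes, 200 gave 1 and 22, and no minimum gave 780 and 1141, as more or fewer genes of low value entered. A ratio of 1.5 gave 82 higher and 177 lower genes and a ratio of 3 gave 1 and 26, by construction. Without the members of the sex-linked, muscle, sensory and nuclear-retained lists, 3 higher and 25 lower genes were left, which still held muscle and noncoding genes outside these lists.

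Hand2 ranged from -1.25 to -1.23 on the log2 scale over scalings and pseudocounts and Gata3 from -0.08 to -0.06. Of 333 values for the 111 genes named by the rule over 3 settings, 323 shifted by less than the SD of like genes. The other 10 moved, all with a pseudocount of 5 and at values listed under 10 on side B. That 0 reversed was fixed in advance. Scaling and centring shifted log2 ratios by at most 0.016, and a pseudocount cannot change the sign of a ratio. Of 13 lists outside the central 95%, 10 stayed outside in all 3 list settings. Autonomic transcription factors came inside without expression matching, and skeletal muscle and sensory neurons had under 5 members at a mean of at least 100, where axon injury (98.3rd percentile) and apoptosis (1.62nd) moved outside. What depth limits was not assessed, since it is not known whether the column sums are read totals.

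No paired analysis was possible because each side holds 1 column and the table names no replicate. For the same reason no replicate was left out. The planned comparisons within and between the Hand2 and Gata3 lines, with their alternatives, were not run, because the table names no line. Planned scalings that model read counts were run while the values were taken as counts, and were left out when the values were treated as normalised.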

Other observations

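The lists and tests in this part were drawn up after the table had been examined. The tests chosen after their results were seen are that of the fixed muscle list, later restated in terms of like genes, and that of all genes by GC content. The lists of MHC class II genes and of the 18 nuclear and splicing-related transcripts were drawn from genes seen to differ, and the 4 lists of X escape, other muscle, other sensory and other nuclear-retained genes from genes not seen. Genes named here outside the lists fixed beforehand were chosen after their values were seen.

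Genes of MHC class II antigen presentation, the machinery by which professional antigen-presenting cells display peptides, were higher on side B. Their 8 detected members, all higher, had a median log2 ratio of 0.68, and 7 lay above the central 95% of their like genes. The class II chain genes H2-Ab1 and H2-Aa had values of 607 and 1055 and 795 and 1249 on sides A and B, the invariant chain gene Cd74 had 1962 and 2966, and the protease gene Ctss had 392 and 665. Macrophage genes, 17 of 18 of them higher, had a median of 0.44 between the same sides, and interferon response genes, which include class I genes, had -0.45. Reads shared between H2 genes make their single values uncertain.

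Among genes outside every list, the collagen gene Col5a3 had values of 4870 and 1696 and the sodium iodide symporter gene Slc5a5 had 580 and 280. Hoxb5, a homeobox gene of trunk identity, had 116 and 19 and Hoxd4 had 93 and 35. The authors' deposited table gives Col5a3 an adjusted p of 3.52e-23, Slc5a5 0.0111, Hoxb5 0.0129 and Hoxd4 1.0.

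Sex-linked transcripts differed between the sides, with Y-linked genes listed at 0 and Xist 14.0-fold higher on side B. A candidate explanation is a different mix of male and female mice in the pools. The 5 X-linked genes that escape inactivation, tested without Eif2s3x, whose value was known, had a median log2 ratio of 0.24, at the 99.7th percentile of random lists, the direction this explanation needs. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 1206, 587, 483 and 282 on side A and 0 on side B, which leaves no sign of male tissue on side B. Their values argue against a genotype effect confined to cells with the Dbh-driven Cre, since the pools also held other cell types. A genotype effect on these genes was not tested otherwise, and the sex of the pooled mice is not given in the labels used here. Sex and genotype cannot be separated for other genes with 1 column per side.

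Skeletal muscle and sensory neuron transcripts were lower on side B. Whether muscle was carried over into side A at dissection stays open, since the fixed muscle list, at -4.22, is the pattern itself and tests nothing further. Muscle genes outside that list had a median of -0.88 over 11 genes, under their random lists but short of the -1 set beforehand, and several are also expressed in ganglia. For carried-over sensory ganglion tissue, 6 further sensory neuron genes had a median of -0.056, at the 31.9th percentile. That met the limit set beforehand for a result against carry-over. Among them, however, Pirt, at 13393 and 12547, has a baseline that would hide a small share. Whether sensory tissue or a loss of these transcripts from sympathetic neurons lies behind Slc17a6 and Scn10a cannot be told apart with so few genes.

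A group of nuclear and splicing-related transcripts was lower on side B, with a median log2 ratio of -1.02 over 18 genes, among them Meg3 (values of 19461 and 5631), Snhg11 (11843 and 3670), Miat (2497 and 688), Malat1 (1575 and 764) and Neat1 (3427 and 1721). After a correction for length that moved ribosomal protein genes from 0.20 to 0.09, the group's median stayed at -0.97 (quartiles -1.38 and -0.75). The medians of all genes in 20 bins of length ran only from -0.064 to 0.141, so this correction could not move the group far. Those bin medians argue against a broad length bias as the whole cause. The correction for GC content left the group's median at -1.03 but hardly moved any list and tested nothing. Among all genes in 20 bins of GC content the lowest median was -0.041, which argues against a broad GC bias as the whole cause. A smaller share of nuclear or incompletely spliced RNA on side B may contribute, since 33 other such transcripts had a median of -0.21, at the 0th percentile, with 29 lower and 4 higher. That share could differ through RNA extraction or through the cells themselves, the table holds no intron values to separate these, and most of the size of the pattern is unaccounted for.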
